A study of Arabidopsis thaliana with 9 samples.

How the data were processed

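The data were gene-level RNA sequencing counts of Arabidopsis thaliana leaves of the ecotype Columbia, with 9 libraries in 3 groups of 3. The groups were named by the agent in the labels. CK was taken as the group without silver, since the labels name no other control, Ag+ stands for silver ions and AgNPs for silver nanoparticles. The labels give 6 days in MS medium, a standard plant culture medium, and state neither the dose nor the length of exposure. Tissue and age stand under unrelated tags there, so the organ was taken from the source field and the series title. The labels speak of pooled RNA and do not say that the 3 libraries of a group came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

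Per the labels' protocols, RNA was extracted with TRIzol, depleted of ribosomal RNA with a total RNA kit, and sequenced as paired 150 bp reads in a single Illumina lane, so no batch could be told apart. The submitters' processing notes name HISAT2, a read aligner, and the genome build TAIR10. The counting tool, its version, its strand setting and the gene annotation are not given in the sources used here. The deposited values were whole-number counts per gene, not normalized, with 1 column per library and no pooled column. Reads of near-identical copies, such as the LHCB1, LHCB2, KIN and VSP families, may have been split or dropped by the authors' counting, so the values of single copies are uncertain. Reads of overlapping or antisense genes cannot be told apart without the strand setting.

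The table held 38202 gene rows, of which 11452 were at 0 in all 9 libraries. No row stood for unassigned reads. Symbols and descriptions came from a RefSeq gene table of the assembly TAIR10.1, which matched 37751 identifiers and left 451 without a name. Its coordinates were used only to mark the ribosomal DNA region, the 19 rows within 10 kb of an annotated nuclear ribosomal RNA gene. Its assembly is not the build named in the notes. These rows also counted as ribosomal RNA genes where such genes were left out.

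Total counts were 19876151, 17540834 and 17454525 in CK 1 to 3, 16884010, 19282410 and 17096937 in Ag+ 1 to 3, and 17293516, 19631828 and 17673405 in AgNPs 1 to 3. Replicate pairs were compared by a chi-square statistic on genes with at least 10 counts in the pair. It lay between 8.99 and 64.2 per degree of freedom, above counting noise alone, which separate libraries of 1 RNA pool can also show. It does not tell whether the libraries are independent samples, and each was counted as 1 sample by assumption. Intervals and floors given for low counts cover counting error only, since reads amplified by PCR are not independent molecules.

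The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with robust dispersions on the counts of all 9 libraries in 1 fit with the group as the only term. The filter filterByExpr kept 19889 genes, TMM factors scaled the libraries, and p-values were two-sided and adjusted by Benjamini-Hochberg over these genes for each comparison. Genes with an adjusted p under 0.05 were called. CPM, the counts scaled by library size, used TMM-scaled sizes and is given as mean ± SD over the 3 libraries of a group. Fold changes come from the edgeR fit and are given with an approximate standard error (SE) on the log2 scale. This SE was the size of the log2 fold change divided by the square root of the F statistic of its test. Where 1 of the groups compared held 1 to 3 counts in all, the ratio of the summed counts is given with a 95% interval (exact binomial), and where it held 0 the fold is a bound against 3 counts over the group. The biological coefficient of variation was 22.5%.

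Before the data were examined, the groups, the tests, the alternatives, 28 gene lists and the rule for the genes named in the text were fixed. The lists held 437 entries. Of these, 11 were left out because the description at the locus in the reference table did not name the gene, which left 426, and 3 loci stood in 2 lists. The lists covered copper and superoxide dismutases, metallothioneins and phytochelatins, iron deficiency, iron storage, sulfate assimilation, ethylene, antioxidant enzymes, glutathione transferases, heat shock, jasmonate, salicylate, camalexin and indole glucosinolates, aliphatic glucosinolates, nuclear-encoded photosynthesis, chlorophyll synthesis, flavonoids, auxin, abscisic acid with cold and drought, cell wall loosening, aquaporins, cell division, DNA damage, senescence, phosphate starvation, nitrate response, the circadian clock, root markers and seed storage. Each was tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, two-sided and adjusted over the 28 lists, and again with a correlation estimated from the data. Called members were counted with p adjusted over all genes tested and adjusted over the list alone. Medians of the lists were the same with low-count members at their bounds.

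The naming rule took, for each comparison, the 7 largest rises and the 7 largest falls among called genes with a mean of at least 5 CPM over the 6 libraries and no overlap between the groups, with ribosomal, transfer and small nucleolar RNA genes left out. It added 2 called members with the smallest adjusted p from each of the 7 lists with the most called members, the clock, root and seed lists left out. It always named CSD1, CSD2, CCS, FSD1, COPT2, EBF2, ERF1, PDF1.2, PR1, APX2, HSP101 and IRT1. Other list members named in the text were chosen after their values were seen, to fill the counts of their lists. A gene that the rule took is not reported here.

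Alternatives were DESeq2 1.42.0 and limma voom in place of edgeR, RLE or upper-quartile factors, no low-count filter or at least 1 CPM in every library of a group, the replicate number as a block, only the 6 libraries compared, the counts without plastid, mitochondrial and ribosomal RNA genes, a threshold of at least 2-fold, and each of the 9 libraries left out in turn. After the data were seen, fits were added with the block in the 6 libraries compared, with the mean log2 CPM of HSP101, HSP70, HSP90.1, HSFA2 and ROF2 as a covariate, and without AgNPs 1 and CK 3. Libraries with the same number in Ag+ and CK deviated together from their group means, with correlations across genes of 0.12, 0.19 and 0.23, so in that comparison the numbers were read as pairs. This comes from the data and not from the labels. AgNPs 1 and Ag+ 2, with unlike numbers, reached 0.291, so values of this size do not establish pairs and the reading is an assumption.

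The method was tested on simulated counts for 19889 genes with the real means and library sizes. Of 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold, edgeR recovered 1.5%, 31.3% and 84.8% in the simulated comparison of Ag+ against CK, with 5 false calls of 83. For AgNPs against CK it recovered 1.5%, 35.8% and 78.8% with 7 false calls of 84, and for AgNPs against Ag+ 7.5%, 44.8% and 84.8% with 8 of 99. Changes of 2-fold or less were therefore mostly missed in these simulations. They gave 83, 84 and 99 calls, against 1108, 660 and 136 in the data. The adjusted threshold eases as more genes change, so these rates may not carry over to the data. DESeq2 recovered more, 53.7% of the 2-fold changes for Ag+ against CK, and made 35 false calls of 139. Other tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.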

Results

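Transcript levels were measured by RNA sequencing in leaves of Arabidopsis thaliana, in 3 libraries without silver (CK), 3 exposed to silver ions (Ag+) and 3 exposed to silver nanoparticles (AgNPs). Total counts per library ranged from 16884010 to 19876151, and 19889 genes had enough counts to be tested. In a principal component analysis of log2 CPM, the first component (28.9% of the variance) separated the CK libraries, at -55.51 to -38.94, from the 6 silver libraries, at 12.36 to 34.44. The second component (20.2%) placed the Ag+ libraries at -33.42 to -18.09 and the AgNPs libraries at 19.02 to 44.54, and on the third (15.9%) AgNPs 1 stood apart at -64.85.

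Several gene groups differed between libraries of the same group. Root markers, read here as transcripts of another organ, had a median of 4.09 CPM over 14 tested genes in AgNPs 1 and of 0.733 to 1.28 CPM in the other 8 libraries. Their sum was 1891.9 to 2042.3 CPM in CK, 2154.1 to 2782 in Ag+, and 3335.6, 2437.5 and 2275.8 in AgNPs 1 to 3. By the sum, each silver library lay above each CK library. Heat-shock genes summed to 1276 CPM in CK 3 against 214 and 192 in CK 1 and CK 2, to 385 in Ag+ 3 against 156 and 127 in Ag+ 1 and Ag+ 2, and to 435, 1420 and 1853 in AgNPs 1 to 3. Nuclear-encoded photosynthesis genes were lowest in the library of each group with the most heat-shock RNA, with medians of 2479, 2393 and 1395 CPM in CK 1 to 3, 4701, 5333 and 3631 in Ag+ 1 to 3, and 4754, 2954 and 2616 in AgNPs 1 to 3. Protein-coding genes took 97.9% to 99.2% of the counts although the labels name a kit for total RNA. Genes of the ribosomal DNA region took 0.669% to 1.42% of the counts in CK, 0.243% to 0.342% in the Ag+ libraries and 0.354% to 1.24% in the AgNPs libraries, mitochondrial genes 0.0231% to 0.0412%, 0.0104% to 0.0143% and 0.0142% to 0.0446%, and plastid genes 0.0284% to 0.0509%, 0.0182% to 0.0247% and 0.0281% to 0.0507%. The ranges of Ag+ and CK did not overlap in any of the 3 shares. The chloroplast transcript psbA had 198 to 803 counts per library and the small RNA of the signal recognition particle 0 to 3.

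**Figure D1:**
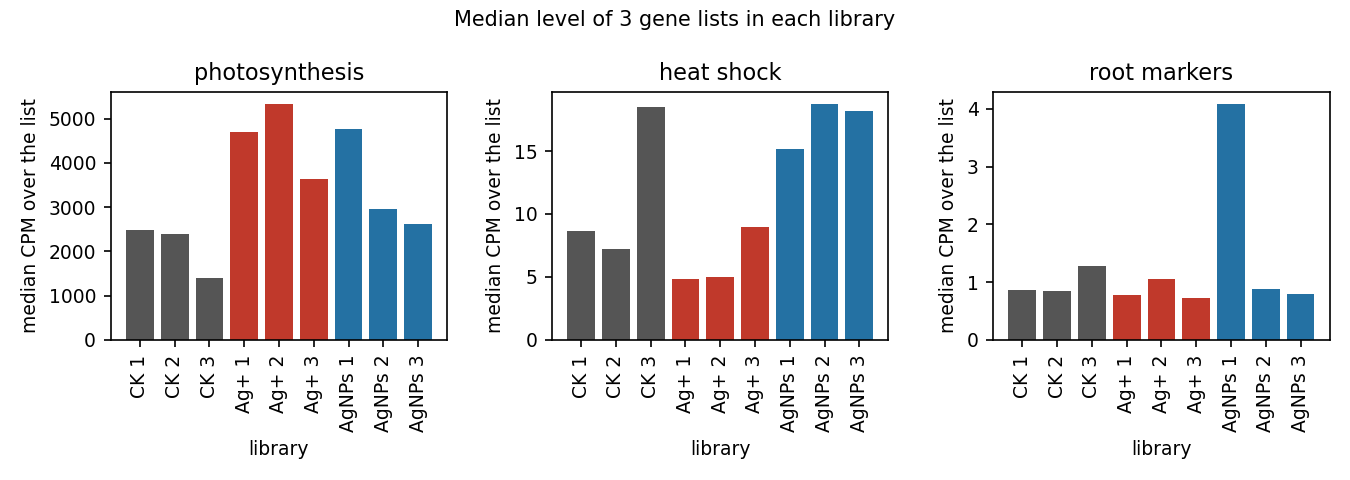
Median CPM of the nuclear-encoded photosynthesis, heat-shock and root-marker lists in each of the 9 libraries, with bars from 0 coloured by group. Root markers reached 4.09 CPM in AgNPs 1 against at most 1.28 CPM in any other library, and photosynthesis genes were lowest in CK 3 at 1395 CPM.

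The comparison of Ag+ against CK asked how leaves exposed to silver ions differed from leaves without silver. The copper/zinc superoxide dismutases CSD2 (AT2G28190) and CSD1 (AT1G08830), which carry copper and remove superoxide, rose 9.06-fold and 5.33-fold. CSD2 stood at 292 ± 61.6 CPM with Ag+ (SD, n = 3) against 32.2 ± 1.83 in CK (log2 fold change 3.18, SE 0.17, edgeR adjusted p = 4.47e-05), and CSD1 at 191 ± 14.2 against 35.9 ± 4.90 CPM (2.41, SE 0.14, adjusted p = 5.03e-05). CCS (AT1G12520), the chaperone that loads copper into these enzymes, rose 4.06-fold (SE 0.17, adjusted p = 0.000409). FSD1 (AT4G25100), an iron superoxide dismutase, fell from 1253 ± 158 to 669 ± 89.9 CPM (log2 fold change -0.91, SE 0.14, adjusted p = 0.00738). The copper transporter gene COPT2 (AT3G46900) was 4.48-fold lower (SE 0.29, adjusted p = 0.00355). Of the 25 tested genes of the copper list, 5 rose, 3 fell and 17 were not called. The others called were PETE1 for plastocyanin (log2 fold change 1.46), ARPN for plantacyanin (1.76) and ZIP2 for a metal transporter (-1.54). Adjusted over the list alone, 6 were higher and 4 lower. The median of the list was 0.09, and it was not called as a set (camera adjusted p = 0.0785, adjusted p = 0.475 with an estimated correlation). It was called as a set without Ag+ 3 (adjusted p = 0.0369).

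Ethylene was among the lists because silver ions are a known blocker of the ethylene receptors. EBF2 (AT5G25350), an F-box protein that removes the ethylene transcription factor EIN3, was 4.01-fold lower (82.2 ± 22.7 against 20.5 ± 2.34 CPM, SE 0.19, adjusted p = 0.000606). The receptor genes ETR2, ERS1 and ERS2 were 9.32-fold, 3.13-fold and 3.79-fold lower, and CTR1, the kinase that represses the pathway, had a log2 fold change of -0.92. Of the 23 tested ethylene genes 6 fell, 0 rose and 17 were not called, with 8 lower and 0 higher adjusted over the list alone. The median of the list was -0.20 (camera adjusted p = 0.00058, adjusted p = 0.368 with an estimated correlation). Among the largest falls of all genes, ORS1 (AT2G41230), ARL (AT2G44080) and ARGOS (AT3G59900), relatives that act on organ size, were 59.3-fold, 22.5-fold and 19.2-fold lower. ORE1 (AT5G39610), a NAC transcription factor of leaf senescence, was 40.7-fold lower, and the uncharacterized gene AT5G57760 dropped from 1017 counts in CK to 2 with Ag+, a ratio of 447 (95% counting interval 123.5 to 3699). AT2G36690, of the 2-oxoglutarate oxygenases, had a log2 fold change of -3.91 and AT1G07160, a protein phosphatase 2C, was 15.4-fold lower (adjusted p = 0.0191). The call of AT1G07160 was lost without Ag+ 1, Ag+ 2 or Ag+ 3 and with limma voom (adjusted p = 0.0927).

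**Figure D2:**
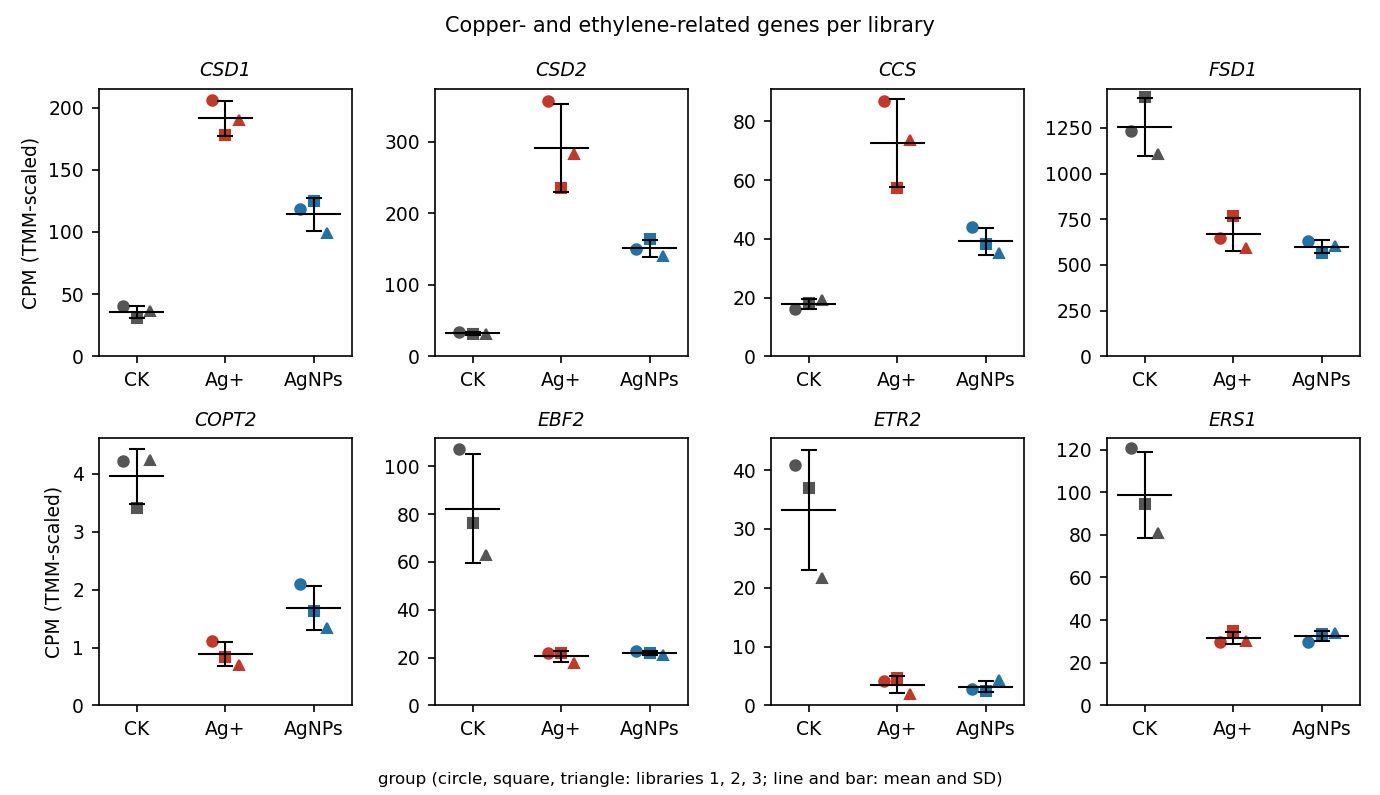
CPM of CSD1, CSD2, CCS, FSD1, COPT2, EBF2, ETR2 and ERS1 in each library, with points for libraries, a line for the group mean and a bar for the SD (n = 3). CSD2 averaged 32.2 CPM in CK, 292 with Ag+ and 151 with AgNPs, and EBF2 82.2, 20.5 and 21.9 CPM.

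Of 26 tested nuclear-encoded photosynthesis genes, 16 rose for Ag+ against CK, 0 fell and 10 were not called, and 21 were higher adjusted over the list alone. LHCB1.2 (AT1G29910), a chlorophyll-binding protein of photosystem II, stood at 6016 ± 1392 against 1780 ± 609 CPM (log2 fold change 1.76, SE 0.30, adjusted p = 0.0103), and LHCB6 (AT1G15820) rose as well (SE 0.26, adjusted p = 0.0104). The median of the list was 1.05 (camera adjusted p = 1.61e-15, adjusted p = 0.368 with an estimated correlation). Chlorophyll synthesis genes had the same median, 1.05 (camera adjusted p = 8.41e-08, adjusted p = 0.368 with an estimated correlation), and 4 of 9 rose, 0 fell and 7 were higher adjusted over the list alone. These were GUN4 (adjusted p = 0.000657), CAO for chlorophyll b synthesis (log2 fold change 1.78), PORB (1.14) and PORC (0.63). Of the heat-shock list, whose level within each group was highest where photosynthesis was lowest, 1 of 16 genes fell, the transcription factor gene HSFA7A (-1.44, SE 0.20), also adjusted over the list alone. Its median was -1.40 (camera adjusted p = 0.0286, adjusted p = 0.583 with an estimated correlation), and this call was lost without CK 3 (adjusted p = 0.68) or Ag+ 2 (0.107). The chaperone gene HSP101 (AT1G74310) had a log2 fold change of -1.47 (SE 0.73, adjusted p = 0.324), and with the libraries paired by number in the 6 libraries compared -1.16 (adjusted p = 0.0414). Called photosynthesis genes numbered 5 without CK 2, 10 without CK 3, and 2 without either Ag+ 1 or Ag+ 2, and chlorophyll genes 2 without CK 2.

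Defence and stress hormone genes were among the largest rises for Ag+ against CK. The thionin gene AT1G66100 rose 68.5-fold, from 0.929 ± 0.273 to 64.0 ± 6.10 CPM (SE 0.32, adjusted p = 4.47e-05). PCC1 (AT3G22231) rose 33.3-fold, its neighbour in name AT3G22235, for a cysteine-rich stress protein, 25.1-fold and LURP1 (AT2G14560) 19.9-fold. ESP (AT1G54040), which diverts glucosinolate breakdown, had a log2 fold change of 4.12. Of 18 jasmonate genes, 7 rose, 0 fell and 11 were not called (10 higher and 1 lower adjusted over the list alone), among them VSP2 for a storage protein of leaves, 22.9-fold, and AOS for the first enzyme specific to jasmonate (log2 fold change 1.73, SE 0.12). The median was 0.66 (camera adjusted p = 2.82e-06, adjusted p = 0.368 with an estimated correlation). Abscisic acid, cold and drought genes had 9 of 19 higher, 0 lower and 10 not called (13 higher and 1 lower adjusted over the list alone). They included KIN2 (2.71, SE 0.21) and COR15B (2.43, SE 0.28), which protect cells in the cold, and the median was 1.14 (camera adjusted p = 4.47e-09, adjusted p = 0.13 with an estimated correlation). In the salicylate list of 14 genes, WRKY38, PR1 and PR5 rose, EDS5 for the salicylate exporter fell (adjusted p = 0.0247), and 10 were not called. The counts were the same adjusted over the list alone, and the median was 0.05 (camera adjusted p = 0.315, adjusted p = 0.805 with an estimated correlation). WRKY38 had 115 counts against 1, a ratio of 131 (95% counting interval 23.0 to 5208), and PR1, a marker of salicylate defence, 80 against 3, a ratio of 30.3 (10.01 to 150.1, adjusted p = 0.014). The flavonoid list had 5 of 16 higher and 0 lower, the same adjusted over the list alone, led by DFR (3.16, SE 0.29) and UF3GT (2.38, SE 0.41) of anthocyanin synthesis. Its median was 0.32 (camera adjusted p = 0.000786, adjusted p = 0.433 with an estimated correlation). Called jasmonate genes numbered 3 without CK 1, Ag+ 1 or Ag+ 2, and salicylate genes 1 without CK 1 or Ag+ 1 and 2 without CK 2. Called flavonoid genes numbered 2 without Ag+ 1, and abscisic acid genes 5 without Ag+ 2. PR1 was not called without CK 1, CK 2 or Ag+ 1, and the salicylate list was called as a set without CK 1 (adjusted p = 0.0306).

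Smaller groups held few called genes for Ag+ against CK. In the sulfate list 3 of 12 rose and 0 fell (4 higher adjusted over the list alone), namely BGLU28 (AT2G44460), a beta-glucosidase induced by sulfur shortage, 20.8-fold, SDI1 (log2 fold change 3.06) and GGCT2;1 (1.54). Its median was 0.51 (camera adjusted p = 0.00203, adjusted p = 0.475 with an estimated correlation), a call lost without CK 2 (adjusted p = 0.0711). The phosphate list had 2 of 11 higher, the non-coding RNAs IPS1 (2.60) and AT4 (2.77). Adjusted over the list alone 4 were higher, and the median was 1.00 (camera adjusted p = 3.18e-06, adjusted p = 0.368 with an estimated correlation). Without CK 3 there were 6 called genes. Of 15 aquaporin genes, which encode water channels, PIP2;1 (1.48), PIP2;6 (0.67) and TIP2;2 (1.33) rose and 12 were not called. There were 13 higher adjusted over the list alone, and the median was 0.53 (camera adjusted p = 5.28e-08, adjusted p = 0.368 with an estimated correlation). Called aquaporin genes numbered 0 without CK 2, Ag+ 1 or Ag+ 2, 1 without CK 1, Ag+ 3 or AgNPs 2, and 5 without AgNPs 1. Of 11 camalexin and indole glucosinolate genes CYP71A12 (2.82), CYP79B2 (1.00) and CYP79B3 (1.31) rose. Adjusted over the list alone 4 were higher, and the median was 0.38 (camera adjusted p = 0.0178, adjusted p = 0.368 with an estimated correlation). Without Ag+ 1 there were 0 of these and 1 without CK 1, CK 2 or Ag+ 3, and the list was not called as a set without CK 2 (adjusted p = 0.0711) or CK 3 (0.0539).

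The remaining sets called by camera for Ag+ against CK had 0 called genes apart from seed storage. Aliphatic glucosinolates (median 0.33, camera adjusted p = 0.015, adjusted p = 0.573 with an estimated correlation) and cell division (0.38, 0.00189, adjusted p = 0.368 with an estimated correlation, 2 of 8 higher adjusted over the list alone) lay higher. Nitrate response lay lower (-0.32, 0.0242, adjusted p = 0.397 with an estimated correlation, 1 of 9 lower adjusted over the list alone). The calls of aliphatic glucosinolates and nitrate response were lost without CK 1 (adjusted p = 0.0608 and 0.0831) and CK 2 (0.289 and 0.135). The seed list had a median of 5.29 (camera adjusted p = 0.0178, adjusted p = 0.4 with an estimated correlation) and 2 of 3 genes higher, CRA1 (5.30) and OLEO1 (5.29), 3 adjusted over the list alone. Its summed level was 3.28 to 31.6 CPM in the Ag+ libraries against 0.149 to 1.07 CPM in CK. Of its genes 0 were called without CK 1 or CK 2, 1 without Ag+ 1, Ag+ 2 or AgNPs 2, 3 of 5 tested without CK 3 and 4 of 5 without Ag+ 3. Lists not called were metallothioneins (1 of 12 higher, MT3, and 2 adjusted over the list alone, median -0.001, turning to 0.001 with upper-quartile factors, mean -0.09, camera adjusted p = 0.748), iron deficiency (0 of 14, 0.08, 0.763), antioxidants (2 of 21 higher, CAT3 and DHAR1, 3 adjusted over the list alone, median -0.02 with a test upwards, 0.486) and glutathione transferases (2 of 23 higher, GSTF9 and CYP81D11, 3 adjusted over the list alone, 0.21, 0.247). Iron storage (0 of 4, 1 higher adjusted over the list alone, median -0.03 with a mean of 0.15 and a test upwards, 0.573), auxin (1 of 13 higher, IAA6, and 1 higher and 1 lower adjusted over the list alone, 0.26, 0.315) and cell wall loosening (EXPA8 higher and XTH18 lower of 12, also adjusted over the list alone, median 0.10 with a mean of -0.15 and a test upwards, 0.713) were not called. The same held for DNA damage (0 of 5, 0.18, 0.713), senescence (SAG13 higher and ORE1 lower of 10, 2 and 2 adjusted over the list alone, median 0.06 with a mean of -0.18 and a test downwards, 0.763), the circadian clock (0 of 13, 0.52, 0.195, but 0.0415 without Ag+ 3) and root markers (0 of 14, -0.35, 0.57). Called metallothioneins numbered 0 without CK 1, CK 2, CK 3, Ag+ 1, Ag+ 2, AgNPs 2 or AgNPs 3, and glutathione transferases 1 without CK 3, Ag+ 1 or Ag+ 2. Auxin genes numbered 2 without CK 3 and 0 without CK 2 or any of the Ag+ and AgNPs libraries, and cell wall genes 1 without CK 1 or Ag+ 3 and 0 without CK 2, Ag+ 1 or Ag+ 2.

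In all, edgeR called 1108 genes between Ag+ and CK, 701 higher and 407 lower, of which 413 and 265 changed at least 2-fold. The groups did not overlap in 4642 genes (23.3%, against 10% by chance with 3 libraries a group). The count was 674 without CK 1, 564 without CK 2, 521 without Ag+ 1, 419 without Ag+ 2 and 657 without Ag+ 3, and 2003 without AgNPs 1 and CK 3. Of the genes named by the rule, FSD1 did not pass the test of at least 2-fold. The Ag+ libraries also held smaller shares of ribosomal, mitochondrial and plastid RNA than CK, and whether a difference in preparation lies behind part of these calls was not tested. Of the 30 genes named by the rule, 28 were called in each of the 9 fits that left out a library. Camera called 15 of the 28 lists, 12 higher and 3 lower, and 0 with an estimated correlation, where 3 lists had an unadjusted p under 0.05.

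The comparison of AgNPs with CK asked the same of silver nanoparticles. CSD2 rose 4.69-fold, to 151 ± 11.8 CPM (n = 3, SE 0.16, adjusted p = 0.000235), and CSD1 3.18-fold, to 114 ± 13.3 CPM (SE 0.14, adjusted p = 0.000477). CCS rose 2.19-fold (SE 0.17, adjusted p = 0.007), FSD1 had a log2 fold change of -1.06 (SE 0.14, adjusted p = 0.00472), and COPT2 of -1.24 (SE 0.28, adjusted p = 0.0408). With PETE1 (0.91) and FSD3 (-0.58), 4 of 25 copper genes rose, 3 fell and 18 were not called, with the same counts adjusted over the list alone and a median of 0.04 (camera adjusted p = 0.848, adjusted p = 0.921 with an estimated correlation). COPT2 was not called with 7 of the 9 libraries left out in turn, namely CK 1, CK 2, CK 3, Ag+ 2, Ag+ 3, AgNPs 2 and AgNPs 3, nor with the replicate block (adjusted p = 0.0516), only the 6 libraries compared (0.0689) or the heat-shock covariate (-1.15, adjusted p = 0.0635). The count of called copper genes was 4 without CK 2, CK 3, AgNPs 2 or AgNPs 3.

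Part of the ethylene list fell with AgNPs as well. EBF2 had a log2 fold change of -1.91 (SE 0.19, adjusted p = 0.00105) and ERS1 of -1.60 (SE 0.16, adjusted p = 0.00104), and ETR2 was 10.4-fold lower. ERS2 (-2.36) and CTR1 (-0.81) fell too. Of the 23 tested genes 6 fell, 0 rose and 17 were not called, and 7 were lower adjusted over the list alone. The median was -0.14 (camera adjusted p = 0.000334, adjusted p = 0.242 with an estimated correlation). EBP (AT3G16770), an ethylene-responsive transcription factor, and AT1G36060, of the same family of DNA-binding proteins, were each 12.0-fold lower, while ACS8 (AT4G37770), for an enzyme of ethylene synthesis outside the list, rose 10.1-fold (SE 0.50, adjusted p = 0.00974). Other large falls were ORS1 (49.3-fold lower), ORE1 (43.9-fold lower) and ARL (13.2-fold lower), and AT5G57760, with 0 counts against 1017 in CK, was at least 328-fold lower. ACS8 was not called without CK 2.

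Part of the iron lists changed with AgNPs. The basic helix-loop-helix regulators of iron uptake, almost silent in CK, rose: BHLH100 (AT2G41240) had 325 counts against 1, a ratio of 336 (95% counting interval 59.9 to 13320, adjusted p = 0.00433), and BHLH101 (AT5G04150) 253 against 3, a ratio of 87.3 (29.5 to 426, adjusted p = 0.00646). BHLH38 had a ratio of 252.5 (44.9 to 10010), BHLH39 a log2 fold change of 4.92 (SE 0.97) and BTS, an iron-sensing ubiquitin ligase, of 0.81 (SE 0.13). Thus 5 of 14 genes of iron deficiency rose, 0 fell and 9 were not called. There were 8 higher adjusted over the list alone, and the median was 1.08 (camera adjusted p = 1.74e-07, adjusted p = 0.113 with an estimated correlation). AT2G30766, written into that list as IMA3 and left out because the reference table calls it uncharacterized, rose 14.2-fold (SE 0.72, adjusted p = 0.0247). Ferritin genes, whose proteins store iron, fell in 3 of 4 tested members, also adjusted over the list alone: FER1 (AT5G01600) from 693 ± 267 to 124 ± 36.4 CPM (log2 fold change -2.49, SE 0.33, adjusted p = 0.00534), FER3 (AT3G56090, -1.32, SE 0.21, adjusted p = 0.01) and FER4 (-1.11, SE 0.18). The median of iron storage was -1.22 (camera adjusted p = 6.34e-05, adjusted p = 0.113 with an estimated correlation). IRT1, the iron transporter of the root surface, had 27 counts in AgNPs 1, where root markers were highest, 2 in AgNPs 2 and 0 in the other 7 libraries. Called genes of iron deficiency numbered 2 without CK 2 and 3 without AgNPs 2, and called ferritins 1 without AgNPs 2. FER3 was not called without AgNPs 2 or AgNPs 3, and AT2G30766 not without CK 2, AgNPs 2 or AgNPs 3, nor with only the 6 libraries compared (log2 fold change 3.83, adjusted p = 0.053).

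**Figure D3:**
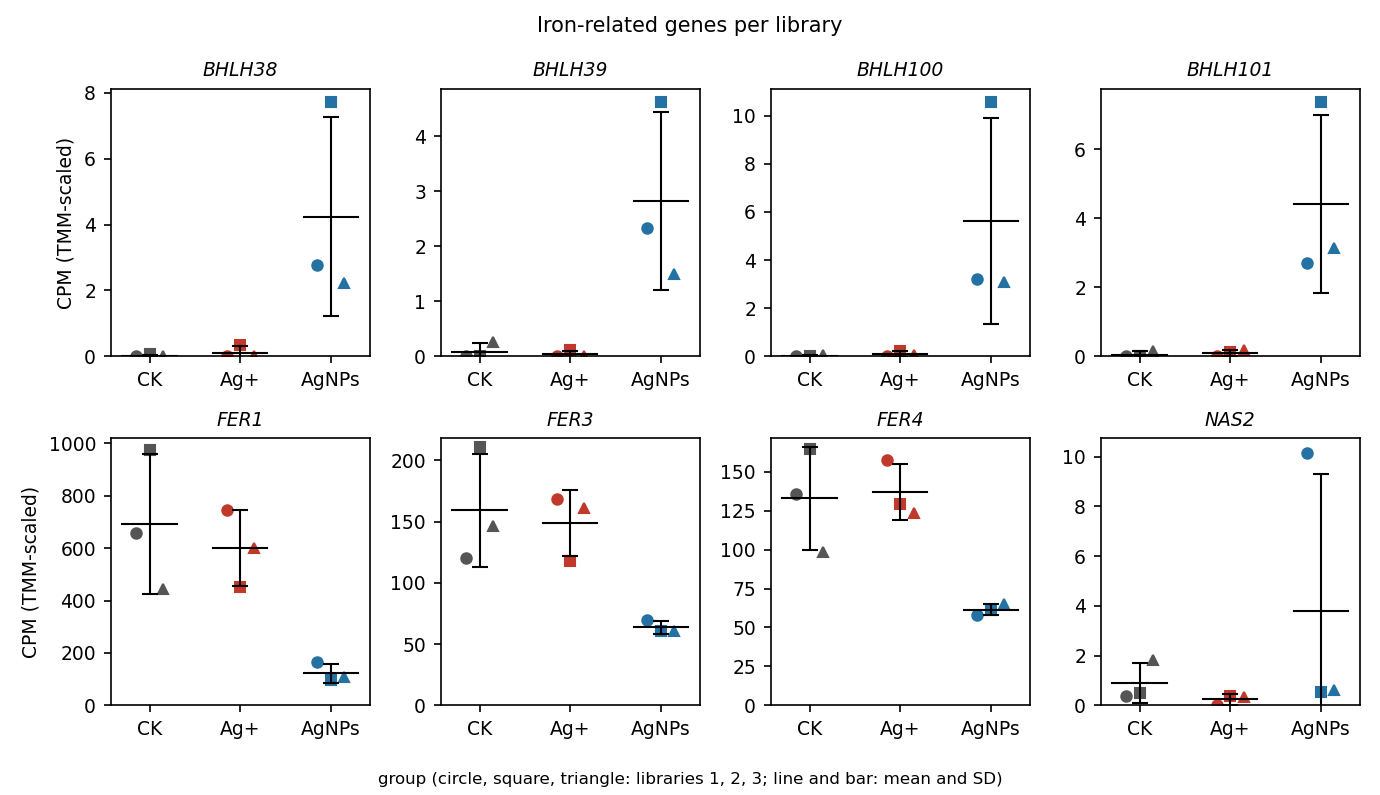
CPM of the regulators BHLH38, BHLH39, BHLH100 and BHLH101, the ferritins FER1, FER3 and FER4, and NAS2 in each library, with points for libraries, a line for the group mean and a bar for the SD (n = 3). FER1 averaged 693 CPM in CK, 600 with Ag+ and 124 with AgNPs, and BHLH100 0.0171, 0.0936 and 5.62 CPM.

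Stress and hormone genes also differed between AgNPs and CK. AT1G66100 rose 45.3-fold, ESP 15.8-fold, VSP2 13.4-fold, COR15A (AT2G42540) 11.5-fold and AT1G14250, a nucleoside phosphatase, 8.84-fold. Of 21 antioxidant genes, UPOX (AT2G21640, log2 fold change 2.22, SE 0.30), AOX1A (AT3G22370, 0.70, SE 0.12), NDB2 (1.49) and DHAR1 (0.72) rose, 0 fell and 17 were not called. The first 3 encode mitochondrial proteins, AOX1A the alternative oxidase. Adjusted over the list alone 7 were higher and 1 lower, and the median was 0.40 (camera adjusted p = 6.34e-05, adjusted p = 0.134 with an estimated correlation). The jasmonate list had 5 of 18 higher, 0 lower and 13 not called, and 7 were higher adjusted over the list alone. AOS had a value of 1.58 (SE 0.12), and the median was 0.66 (camera adjusted p = 2.84e-07, adjusted p = 0.113 with an estimated correlation). In the abscisic acid list KIN2 (2.55, SE 0.20), COR15A, COR15B (1.38), ABF3 for a transcription factor (0.99, SE 0.16) and NCED3 of abscisic acid synthesis (2.17) rose, 14 of 19 were not called, and 14 were higher and 2 lower adjusted over the list alone. The median was 0.89 (camera adjusted p = 1.74e-07, adjusted p = 0.113 with an estimated correlation). Called antioxidant genes numbered 2 without CK 1, CK 2 or Ag+ 2 and 1 without AgNPs 2 or AgNPs 3. Jasmonate genes numbered 3 without CK 1 or AgNPs 2 and 2 without AgNPs 3, and abscisic acid genes 2 without CK 2, 3 without Ag+ 2 or AgNPs 3 and 1 without AgNPs 2. COR15A was not called without CK 2 or AgNPs 2, ABF3 not without AgNPs 2 and AOX1A not without AgNPs 2 or AgNPs 3.

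Photosynthesis genes had a median of 0.72 with AgNPs (camera adjusted p = 1.74e-07, adjusted p = 0.358 with an estimated correlation). Of 26 genes 3 were higher, LHCB1.2 (log2 fold change 1.42), LHCB6 (1.15) and LHCA1 (1.16), and 15 higher and 2 lower adjusted over the list alone. Chlorophyll synthesis had 3 of 9 higher, GUN4 (1.25), CAO (1.46) and PORB (0.88), also adjusted over the list alone, and a median of 0.39 (camera adjusted p = 0.000243, adjusted p = 0.326 with an estimated correlation). Called photosynthesis genes numbered 0 without CK 2, Ag+ 1, AgNPs 1 or AgNPs 2, 1 without Ag+ 2 or AgNPs 3 and 7 without CK 1, and chlorophyll genes 1 without CK 2, Ag+ 1, Ag+ 2, AgNPs 1, AgNPs 2 or AgNPs 3. The heat-shock list, highest in AgNPs 2, AgNPs 3 and CK 3, had 0 of 16 genes called, 0 adjusted over the list alone, and a median of 1.22 (camera adjusted p = 6.34e-05, adjusted p = 0.326 with an estimated correlation). HSP101 had a log2 fold change of 0.96 (SE 0.71, adjusted p = 0.565), and 2.60 (adjusted p = 0.028) without AgNPs 1 and CK 3. The salicylate list had WRKY38, with 26 counts against 1, a ratio of 26.9 (95% counting interval 4.42 to 1103), and PR5 (0.97) higher of 14, 3 adjusted over the list alone, and a median of 0.27 (camera adjusted p = 0.0152, adjusted p = 0.459 with an estimated correlation). PR1, with 26 counts against 3, was not called (ratio 8.97, 2.75 to 46.3, adjusted p = 0.13). The salicylate set was not called without CK 2 (adjusted p = 0.528) or AgNPs 1 (0.157), and its called genes numbered 0 without CK 2 or AgNPs 2 and 1 without CK 1, Ag+ 1, Ag+ 2 or AgNPs 3.

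For AgNPs against CK the aliphatic glucosinolate list had a median of 0.72 (camera adjusted p = 1.08e-08, adjusted p = 0.187 with an estimated correlation). In it MYB76 (log2 fold change 2.48), MAM1 (0.98) and IPMI2 (0.72) rose, 14 of 17 were not called, and 11 were higher adjusted over the list alone. The camalexin and indole list had a median of 0.92 (camera adjusted p = 1.81e-05, adjusted p = 0.113 with an estimated correlation). In it CYP71A12 (2.70), CYP79B2 (1.13) and CYP83B1 (1.13) rose of 11, and 6 adjusted over the list alone. Glutathione transferases had a median of 0.51 (camera adjusted p = 6.34e-05, adjusted p = 0.134 with an estimated correlation). Here GSTU9 (1.84) and GSTF9 (0.77) rose of 23, and 5 adjusted over the list alone. Phosphate genes had a median of 1.06 (camera adjusted p = 3.02e-07, adjusted p = 0.227 with an estimated correlation). Here IPS1 (2.93) and AT4 (2.04) rose of 11, and 4 adjusted over the list alone. In the auxin list the repressor genes IAA6 (3.04) and IAA19 (1.16) rose and TAA1 of auxin synthesis fell (-0.60), of 13. There were 5 higher and 1 lower adjusted over the list alone, and the median was 0.35 (camera adjusted p = 0.00932, adjusted p = 0.113 with an estimated correlation). Called aliphatic genes numbered 10 without CK 3, 1 without CK 1, CK 2, Ag+ 1 or AgNPs 1 and 0 without AgNPs 2 or AgNPs 3. Indole genes numbered 0 without CK 2 and 1 without AgNPs 2 or AgNPs 3, glutathione transferases 1 without CK 1, CK 2 or AgNPs 2. Phosphate genes numbered 6 without CK 3, and auxin genes 1 without CK 2, Ag+ 1, Ag+ 2, Ag+ 3, AgNPs 2 or AgNPs 3.

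Further sets called by camera for AgNPs against CK were flavonoids (DFR at 2.38 and UF3GT at 1.82 higher of 16, 4 adjusted over the list alone, median 0.06, camera adjusted p = 0.011, adjusted p = 0.459 with an estimated correlation), aquaporins (0 of 15, 1 higher adjusted over the list alone, 0.24, 0.0216, adjusted p = 0.459 with an estimated correlation) and seed storage (CRA1 at 4.59 higher of 3, 2 adjusted over the list alone, 3.94, 0.0339, adjusted p = 0.373 with an estimated correlation). The flavonoid set was not called without CK 1 (adjusted p = 0.254) or CK 2 (0.0802), the aquaporin set not without CK 3 (0.0688) or AgNPs 1 (0.367), and the seed set not without AgNPs 1 (0.0762). Not called were sulfate (0 of 12, 1 higher adjusted over the list alone, median 0.18, camera adjusted p = 0.065), senescence (NYC1 at -0.80 and ORE1 lower of 10, also adjusted over the list alone, -0.45, 0.075), nitrate response (NRT3.1 at 1.00 higher of 9, 2 adjusted over the list alone, 0.12, 0.152) and root markers (0 of 14, 1 higher adjusted over the list alone, 0.89, 0.178). The sulfate set was called with CK 1, CK 3, AgNPs 2 or AgNPs 3 left out (adjusted p = 0.0131, 0.0361, 0.018 and 0.0141), senescence without CK 2 (0.0428) or CK 3 (0.0361), nitrate without CK 2 (0.0382), and root markers without AgNPs 2 (0.0205) or AgNPs 3 (0.00661). The metallothionein list was not called (MT2A at -0.84 lower of 12, also adjusted over the list alone, mean 0.02 and a test downwards, 0.552). Its median was -0.002, turning to 0.003 with RLE and 0.002 with upper-quartile factors. Cell wall loosening (EXPA8 higher of 12, 3 adjusted over the list alone, median -0.16 with a mean of 0.01 and a test upwards, 0.848), cell division (0 of 8, 0.11, 0.426), DNA damage (0 of 5, 1 higher adjusted over the list alone, 0.06, 0.426) and the circadian clock (0 of 13, 3 higher and 2 lower adjusted over the list alone, 0.05, 0.426) were not called either. Called flavonoid genes numbered 1 with any library but CK 3 or Ag+ 3 left out, and the called metallothionein and cell wall genes 0 without CK 2, AgNPs 2 or AgNPs 3, with 2 cell wall genes without CK 1, CK 3 or AgNPs 1. Senescence genes numbered 1 without CK 2, AgNPs 2 or AgNPs 3. The called seed gene was lost with any library but Ag+ 2 or Ag+ 3 left out, and nitrate genes numbered 2 without AgNPs 1 and 0 without CK 1, CK 2, CK 3, Ag+ 2, AgNPs 2 or AgNPs 3.

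In all, 660 genes were called between AgNPs and CK, 444 higher and 216 lower, of which 305 and 127 changed at least 2-fold, and the groups did not overlap in 4491 genes (22.6%, against 10% by chance). The count was 245 without CK 2, 224 without AgNPs 2 and 261 without AgNPs 3, 351 with only the 6 libraries compared, and 1603 without AgNPs 1 and CK 3. With the replicate block in the 6 libraries compared, chosen after the data were seen, the calls of COPT2 (-1.25), FSD1 (-1.06), BHLH101 (6.16), AT2G30766 (4.12), FER3 (-1.29), UPOX (2.26), AOX1A (0.71) and ACS8 (3.46) ended, and ABF3 and AOX1A did not pass the test of at least 2-fold. Of the 31 genes named by the rule, 24 were called in each of the 9 fits that left out a library. Camera called 18 of the 28 lists, 16 higher and 2 lower, and 0 with an estimated correlation, where 8 lists had an unadjusted p under 0.05.

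Both silver comparisons called 435 of the same genes, 308 higher in both, 127 lower in both and 0 in opposite directions. Lists that were independent would share 15.6 and 4.42. Part of the excess may come from the shared CK libraries, which are too few to be split. Across the 19889 genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.646 and a covariance of 0.252. In 20 simulations of unchanged groups that shared 1 simulated CK group, these averaged 0.494 (at most 0.510) and 0.0560 (at most 0.0583). The Spearman correlation of 0.472 did not exceed the simulated ones (mean 0.460, at most 0.473). Nor did the share of genes with the same sign, 66.3% (mean 66.4%, at most 67.0%). The simulations drew each gene independently and without pairs of libraries, so their range may be too narrow. They cannot tell how much of any of these values comes from the shared CK libraries. The overlap was 178 without CK 2, 274 without Ag+ 1, 235 without Ag+ 2, 185 without AgNPs 2 and 204 without AgNPs 3.

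**Figure D4:**
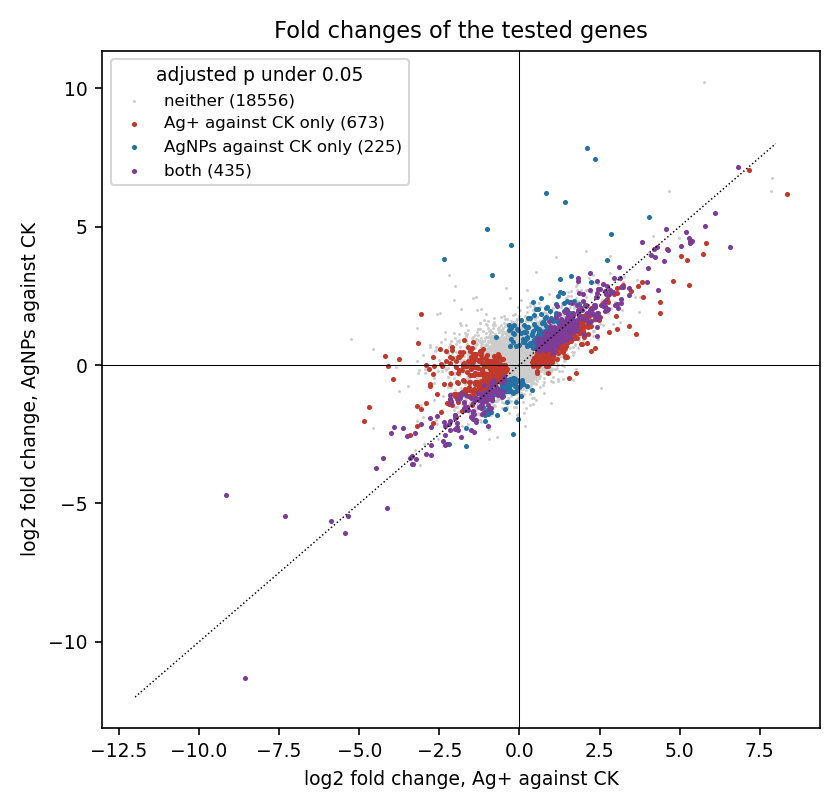
Log2 fold change with Ag+ against CK (x axis) and with AgNPs against CK (y axis) for each of the 19889 genes, coloured by call, with a dotted line of equality. Of the genes, 435 were called in both comparisons, 673 only for Ag+ and 225 only for AgNPs, with 0 called in opposite directions.

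AgNPs and Ag+ were also compared directly, which tests the difference between the silver forms. Some calls were iron genes: BHLH100 was 53.7-fold higher with AgNPs than with Ag+ (log2 fold change 5.75, SE 0.84, edgeR adjusted p = 0.035), BHLH101 42.0-fold (5.39, SE 0.84, adjusted p = 0.035) and AT2G30766 73.3-fold (6.20, SE 0.90, adjusted p = 0.035). FER1 was 4.86-fold lower (124 ± 36.4 against 600 ± 146 CPM, n = 3, SE 0.33), FER3 2.34-fold lower (SE 0.21) and FER4 2.23-fold lower (SE 0.18). With BHLH39, at 160 counts against 2 (ratio 72.8, 95% counting interval 19.8 to 606.5), and FRO3 for a ferric reductase (0.73), 4 of 14 genes of iron deficiency rose, 0 fell and 10 were not called. Adjusted over the list alone 9 were higher, and the median was 0.82 (camera adjusted p = 8e-08, adjusted p = 0.253 with an estimated correlation). Of iron storage 3 of 4 fell, and 4 adjusted over the list alone, with a median of -1.19 (camera adjusted p = 5.74e-07, adjusted p = 0.22 with an estimated correlation). The copper enzymes were lower with AgNPs than with Ag+, CSD2 by 1.93-fold (SE 0.15, adjusted p = 0.035), CSD1 by 1.68-fold (SE 0.14, adjusted p = 0.0475) and CCS by 1.86-fold (SE 0.16, adjusted p = 0.0479), so that 3 of 25 copper genes fell, 0 rose and 22 were not called. There were 2 higher and 6 lower adjusted over the list alone, with a median of -0.09 (camera adjusted p = 0.00613, adjusted p = 0.306 with an estimated correlation). With the heat-shock covariate, chosen after the data were seen, the calls of BHLH100 (4.83, adjusted p = 0.114), BHLH101 (3.79, 0.106), AT2G30766 (5.02, 0.0621), FER1 (-1.70, 0.0539), FER3 (-1.15, 0.0941), FER4 (-0.82, 0.0913), CSD2 (-0.93, 0.0617), CSD1 (-0.72, 0.0856) and CCS (-0.92, 0.0736) ended. With limma voom those of BHLH100 (5.77, adjusted p = 0.104), BHLH101 (5.397, 0.0719), AT2G30766 (6.74, 0.0556), FER3 (-1.21, 0.0523), CSD1 (-0.75, 0.0569) and CCS (-0.88, 0.0597) ended. These calls needed each of 5 libraries, since edgeR called 0 genes without Ag+ 1, Ag+ 2, Ag+ 3, AgNPs 2 or AgNPs 3, so 0 copper and iron genes too, though 2374, 2292, 2757, 1907 and 2014 genes then had an unadjusted p under 0.05. Called genes of iron deficiency numbered 7 without CK 3 and copper genes 5 without AgNPs 1, CCS was not called without CK 2, and with RLE factors CSD1 (adjusted p = 0.0504) and CCS (0.0508) lay just above the threshold.

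Other lists held at most 1 called gene between the silver forms. The sulfur-shortage gene BGLU28 was lower with AgNPs (1.80 ± 1.08 against 9.96 ± 1.02 CPM, adjusted p = 0.035). LURP1 was 3.06-fold lower and LOX2 (AT3G45140), the lipoxygenase of jasmonate synthesis, 2.63-fold lower (501 ± 11.3 against 1318 ± 400 CPM). The uncharacterized AT5G35777 was 3.81-fold lower and the F-box gene AT3G23880 2.49-fold lower. SDR5 (AT2G47140) was 8.45-fold higher, AT3G07195, of the RIN4 family of immune proteins, 7.91-fold, EXO70H2 (AT2G39380), of the exocyst, 7.69-fold, AT1G49000 6.76-fold, SHB1 (AT4G25350) 6.17-fold and the lectin receptor kinase gene LECRKA4.1 (AT5G01540) 5.56-fold. Against CK, SDR5, AT3G07195, EXO70H2, SHB1 and LECRKA4.1 were lower with Ag+ (log2 fold changes -2.49, -2.69, -2.93, -1.72 and -2.18) and not called with AgNPs (0.59, 0.29, 0.02, 0.91 and 0.30). AOX1A was 1.77-fold higher (SE 0.12, adjusted p = 0.0348), NRT3.1 of nitrate uptake 3.35-fold and EDS5 2.27-fold. HSFA7A had a log2 fold change of 1.07 (SE 0.20, adjusted p = 0.0498). Not called were FSD1 (log2 fold change -0.15, adjusted p = 0.641), COPT2 (0.93, 0.196), EBF2 (0.09, 0.848), PR1 (-1.75, 0.261) and HSP101 (2.43, 0.187, and 2.52 with an adjusted p of 0.0448 with the replicate number as a block). With the heat-shock covariate the adjusted p passed 0.05 for SDR5 (log2 fold change 3.00 against 3.08 without it), EXO70H2 (2.62 against 2.94), AT1G49000 (2.36 against 2.76), LECRKA4.1 (2.03 against 2.48), HSFA7A (0.97 against 1.07), BGLU28 (-1.68 against -2.49) and LURP1 (-1.22 against -1.61). With limma voom it did for SDR5 (3.06), EXO70H2 (2.98), AT1G49000 (2.71), LECRKA4.1 (2.49), HSFA7A (1.05), AT3G07195 (3.04 against 2.98) and AT5G35777 (-1.90 against -1.93). By edgeR 0 of the genes called here were called without Ag+ 1, Ag+ 2, Ag+ 3, AgNPs 2 or AgNPs 3, and AT3G07195 and HSFA7A not without CK 2 or AgNPs 1 either. Called sulfate genes numbered 2 without CK 2 and 3 without CK 3, jasmonate genes 3 without CK 1 or CK 3 and 2 without CK 2, and antioxidant genes 3 without CK 3 and 2 without AgNPs 1. Heat-shock genes numbered 2 without CK 2, 3 without CK 3 and 5 without AgNPs 1, and nitrate genes 2 without CK 3 and 3 without AgNPs 1.

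As sets for AgNPs against Ag+, heat-shock genes had a median of 2.77 (camera adjusted p = 3.09e-09, adjusted p = 0.306 with an estimated correlation), with 1 of 16 called and 14 higher adjusted over the list alone. Their level was high in AgNPs 2 and AgNPs 3. Antioxidants (median 0.51, camera adjusted p = 0.00526, adjusted p = 0.306 with an estimated correlation, 1 of 21 called, 7 higher and 1 lower adjusted over the list alone), glutathione transferases (0.35, 0.00811, adjusted p = 0.306 with an estimated correlation), aliphatic glucosinolates (0.44, 1.38e-05, adjusted p = 0.34 with an estimated correlation) and nitrate response (0.39, 0.000679, adjusted p = 0.306 with an estimated correlation, 1 of 9 called, 5 higher adjusted over the list alone) lay higher with AgNPs. Root markers, highest in AgNPs 1, had a median of 1.01 (camera adjusted p = 0.0358, adjusted p = 0.686 with an estimated correlation, 1 higher adjusted over the list alone), and 0.738 was the adjusted p without AgNPs 1. Lower with AgNPs lay sulfate (-0.35, camera adjusted p = 0.0206, adjusted p = 0.566 with an estimated correlation, 1 of 12 called, 3 lower adjusted over the list alone), photosynthesis (-0.37, 1.38e-05, adjusted p = 0.46 with an estimated correlation, 1 lower adjusted over the list alone), chlorophyll synthesis (-0.32, 0.00394, adjusted p = 0.415 with an estimated correlation) and aquaporins (-0.41, 3.92e-05, adjusted p = 0.306 with an estimated correlation, 1 lower adjusted over the list alone). The same held for abscisic acid (-0.15, 0.0358, adjusted p = 0.352 with an estimated correlation), cell division (-0.29, 0.00713, adjusted p = 0.352 with an estimated correlation) and senescence (-0.48, 0.0381, adjusted p = 0.306 with an estimated correlation, 1 higher and 3 lower adjusted over the list alone). These set calls were lost for sulfate without Ag+ 1 (adjusted p = 0.142) or AgNPs 3 (0.072), for antioxidants without AgNPs 1 (0.0522), and for glutathione transferases and cell division without Ag+ 2 (0.061 and 0.0607). They were also lost for abscisic acid without Ag+ 1 (0.142), AgNPs 1 (0.0526) or AgNPs 3 (0.0731), for senescence without CK 1 (0.0654), Ag+ 1 (0.0892) or AgNPs 3 (0.0888), and for root markers also without CK 2 (0.0655), CK 3 (0.0692), Ag+ 1 (0.0909) or Ag+ 3 (0.169).

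The other lists were not called for AgNPs against Ag+. Ethylene genes had 0 of 23 called, 0 adjusted over the list alone, and a median of 0.09 (camera adjusted p = 0.594). The jasmonate list had 1 of 18 called, LOX2, 2 higher and 3 lower adjusted over the list alone, and a median of -0.03 with a mean of 0.02 and a test downwards (0.486), and the salicylate list 1 of 14, EDS5, 1 higher and 1 lower adjusted over the list alone, and a median of 0.29 with a mean of -0.10 and a test upwards (0.552). Metallothioneins (0.01 with a mean of 0.11 and a test downwards, 0.703, 1 higher and 3 lower adjusted over the list alone), camalexin (0.55, 0.0557), flavonoids (-0.35, 0.0601), auxin (0.48, 0.0575, 1 higher adjusted over the list alone) and cell wall loosening (0.10, 0.944) had 0 called genes. So had DNA damage (0.05, 0.58), phosphate starvation (0.07, 0.896), the circadian clock (-0.08, 0.552) and seed storage (-0.71, 0.43). Camalexin was called as a set without CK 1, Ag+ 1, Ag+ 3, AgNPs 2 or AgNPs 3 (adjusted p = 0.0089, 0.0385, 0.0265, 0.0213 and 0.0425), flavonoids without Ag+ 2 (0.00763), auxin without Ag+ 3 (0.0423) or AgNPs 2 (0.0474) and seed storage without Ag+ 3 (0.0021).

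In all, 136 genes were called between the silver forms, 101 higher and 35 lower with AgNPs, of which 85 and 14 changed at least 2-fold. Of the 136, 79 were also called for Ag+ against CK, 36 for AgNPs against CK and 9 for both, and the groups did not overlap in 4401 genes (22.1%, against 10% by chance). The count was 0 without Ag+ 1, Ag+ 2, Ag+ 3, AgNPs 2 or AgNPs 3 (unadjusted p under 0.05 in 2374, 2292, 2757, 1907 and 2014 genes), 241 without CK 1, 311 without CK 3 and 444 without AgNPs 1, and 1276 without AgNPs 1 and CK 3. Of the 136 genes, 42 were among the 336 called with the heat-shock covariate and 46 among the 47 called with limma voom. Without a low-count filter the calls of AT3G07195 (2.98), AT1G49000 (2.75) and LECRKA4.1 (2.47) ended, with the replicate block those of AT1G49000 (2.83) and FER3 (-1.23), and with the block in the 6 libraries compared those of AT1G49000 (2.71), CSD1 (-0.72), CSD2 (-0.90) and HSFA7A (1.09). CSD1, CSD2, CCS and AOX1A did not pass the test of at least 2-fold. Of the 22 genes named by the rule, 0 were called in each of the 9 fits that left out a library, and 0 changed sign. Camera called 16 of the 28 lists, 7 higher and 9 lower, and 0 with an estimated correlation, where 4 lists had an unadjusted p under 0.05. Of the genes always named, ERF1, PDF1.2 and APX2 lay below the filter in all 3 groups, with at most 9, 7 and 4 counts in a library, as did IRT1.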

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

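The fits with the replicate block in the 6 libraries compared, with the heat-shock covariate and without AgNPs 1 and CK 3 were tests chosen after the data were seen. RLE factors gave 1095, 669 and 128 called genes for Ag+ against CK, AgNPs against CK and AgNPs against Ag+, upper-quartile factors 1145, 677 and 188, and no low-count filter 1078, 652 and 164. At least 1 CPM in every library of a group gave 1132, 693 and 184, and the counts without plastid, mitochondrial and ribosomal RNA genes 1105, 676 and 142. DESeq2 called 1877, 1431 and 845 genes and 817 in both silver comparisons, and it also made more false calls on simulated data. A change of at least 2-fold left 678, 432 and 99, since it adds a condition to the same test. Limma voom called 47 genes for AgNPs against Ag+. With only the 6 libraries compared, the counts were 351 for AgNPs against CK and 408 for AgNPs against Ag+, and the cause was not tested.

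Leaving out each library in turn gave 419 to 1372 genes for Ag+ against CK, 224 to 809 for AgNPs against CK, 0 to 444 for AgNPs against Ag+ and 178 to 503 in both silver comparisons. A group left with fewer libraries has less power. Called lists then numbered 11 to 17, 15 to 20 and 13 to 18. With all 9 libraries and an estimated correlation they numbered 0, 0 and 0. Without AgNPs 1 and CK 3 the counts of genes were 2003, 1603 and 1276, with 769 in both silver comparisons. With the heat-shock covariate they were 1663, 1132 and 336, with 534 in both. The cause of these increases was not tested.

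With the replicate block, read as paired libraries for Ag+ against CK, 1238 genes and 15 lists were called, and in the 6 libraries compared 1639 genes. Besides HSP101 it ended or made no call of a gene named by the rule for Ag+ against CK. The AgNPs libraries share only a number with the others: AgNPs 1 deviated most like Ag+ 2 (correlation 0.291). For them the block gave 668 genes against CK and 236 against Ag+, and in the 6 libraries compared 195 and 357, and the cause was not tested.

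For the genes named by the rule, 1791 values under the alternatives kept their direction and their side of the threshold, 199 kept their direction and were no longer called, 5 of HSP101 became called and 2 turned. For AgNPs against Ag+, FSD1 went from -0.15 to 0.12 with the heat-shock covariate. EBF2 ranged from -0.001 without Ag+ 3 to 0.14 without Ag+ 2. None of these was called, and the cause was not tested. Depth limits the genes with few counts, such as the iron regulators in CK.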

Other observations

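The tests of root RNA, dilution, heat shock, scaling and harvest time were chosen after the result was seen, and those of other splits and of microRNA targets before. Each comparison of 3 libraries with 3 has 10 splits, too few for a share under 0.05, and for each count of genes or lists 1 split, the real one, gave a result as large. Genes called numbered 1108, 660 and 136 for Ag+ against CK, AgNPs against CK and AgNPs against Ag+, and 0 at most in the other splits. A split that mixes the groups adds any difference between them to the spread, which lowers its calls. An unadjusted edgeR p under 0.05 was reached by 3827, 3374 and 2947 genes in the real splits. In the other splits it was reached by at most 1927, 3017 and 2315. The split with 3017 set AgNPs 1, CK 1 and CK 2 against AgNPs 2, AgNPs 3 and CK 3. Lists called numbered 15, 18 and 16, and 11, 11 and 13 at most in the other splits. For Ag+ against CK, where numbers were read as pairs, 4 of the 10 splits part all 3 pairs, the real one included, and the other splits part 1. Of 100 groupings of the 9 libraries, 1, the real one, gave an overlap of 435 genes or more, as did 1 of the 38 that part the 3 pairs of Ag+ and CK, the real one. This argues against chance only for which libraries form the control, and only if the libraries are independent samples, as was assumed. The 97 groupings with another control gave 0, and the 2 others that kept CK gave 373 and 322.

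With AgNPs, 4 regulators of iron uptake were higher and 3 of 4 ferritins lower, in leaf libraries of which AgNPs 1 also held root markers. Root RNA is argued against as the cause for the regulators: without AgNPs 1 the smallest log2 fold change of BHLH38, BHLH39, BHLH100 and BHLH101 was 5.03 (BHLH39, SE 1.003, adjusted p = 0.0295). Dilution of leaf RNA predicted a fall of the photosynthesis list, which had a median of 0.72 (SD of its members 0.918) and not a fall. That list was also higher with Ag+, so a rise in it could hide dilution. For the 3 ferritins that fell, dilution by root RNA is argued against. FER3 averaged 63.6 ± 5.19 CPM over the AgNPs libraries against 159 ± 46.4 in CK. FER4 averaged 61.4 ± 3.55 CPM against 137 ± 18.0 with Ag+, so neither was low in AgNPs 1 alone. FER1 stood at 98.4 and 107 CPM in AgNPs 2 and AgNPs 3, where the median of the root markers was 0.886 and 0.799 CPM. In AgNPs 1, with a root-marker median of 4.09 CPM, FER1 was higher, at 165 CPM. The summed root markers in AgNPs 2 and AgNPs 3, 2437.5 and 2275.8 CPM, did lie above CK (1891.9 to 2042.3). They lay within the range of Ag+ (2154.1 to 2782), where FER1 averaged 600 CPM and BHLH100 0.0936 CPM. Root RNA in AgNPs 1 stays open for NAS2, F6H1 and ABCG37, picked because they were highest there: their median log2 ratio of AgNPs 1 to the other AgNPs libraries, 3.49, lay above the quartiles of the 14 root markers (1.80 to 2.62) and within their range (0.12 to 3.69), which is too wide to decide. An effect of AgNPs on iron genes stays open, and no biological explanation was tested.

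Of 26 photosynthesis genes 16 were higher with Ag+, while heat-shock genes varied between libraries. With the heat-shock covariate the median log2 fold change was 0.81 (median SE 0.133) against 1.05 without it, and 21 genes were called against 16, which argues against that variation as the whole cause. Scaling was not decided: RLE and upper-quartile factors moved the median of the list only to 1.04 and 1.06, too little to test it, and its excess of 1.06 over the other tested genes (SD of its members 0.944) restates it, since TMM sets the others near 0. Another time of harvest stays open: relative to the 9 other clock genes, the morning genes CCA1, LHY, PRR9 and RVE8 differed from CK by 0.66 with Ag+ (SE between libraries 0.349, exact permutation p = 0.3, with Ag+ 3 inside the range of CK) and by 1.05 with AgNPs (SE 0.216, p = 0.1, the smallest possible), where the photosynthesis list had the lower median of 0.72. Of the 13 clock genes 0 were called for Ag+ against CK, nor was the list (camera adjusted p = 0.195, and 0.0415 without Ag+ 3), and an effect of silver on photosynthesis genes stays open, untested.

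CSD1, CSD2 and CCS, targets of a microRNA made when copper is scarce, were higher with both forms of silver. Loss of such microRNAs may explain this, and would raise their other targets. The set tested here pooled targets of miR398, miR397, miR408 and miR857. Its median therefore does not test the microRNA of the dismutases alone. The 7 others tested had a median log2 fold change of 0.42 (SD 1.27) with Ag+, and 3 of 7 were higher adjusted over these genes alone, LAC4, LAC17 and COX5B-1 (adjusted p = 0.0527 over all genes), and with AgNPs the median was 0.64 (SD 0.626) and 2 of 7 were higher, LAC4 and LAC17. The value with Ag+ lies between those set for and against the explanation. With so few targets, the explanation cannot be told apart from other causes. The 7 were also not all such targets: ARPN, LAC3 and LAC12, of the copper list, are others and were not among them. Of these, ARPN alone was called with Ag+, as higher, and no call was made with AgNPs. Whether counting them would change the outcome was not tested. Of the precursors, whose values were looked at afterwards, MIR398B had 53, 57 and 64 counts in CK 1 to 3, 14, 33 and 17 in Ag+ 1 to 3, and 34, 29 and 34 in AgNPs 1 to 3 (adjusted p = 0.0516 and 0.239 against CK), MIR408 had 15, 23 and 20, 8, 16 and 2, and 10, 29 and 21 (0.431 and 0.976), and MIR398C 15, 14 and 11, 8, 14 and 1, and 6, 7 and 4 (0.683 and 0.434).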
